A study of Homo sapiens with 8 samples.

How the data were processed

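RNA was measured by sequencing in 8 libraries of the human neuroblastoma cell line SH-SY5Y, 2 in each of 4 groups. Cells received 40 nM of siRNA in total with Lipofectamine RNAiMax: 40 nM control siRNA (siCTL), 20 nM siRNA against DDX5 and DDX17 with 20 nM control siRNA (siDDX5/17), 20 nM siRNA against REST with 20 nM control siRNA (siREST), or 20 nM of each targeting siRNA (double knockdown). The control siRNA dose therefore differed between groups, from 40 nM in siCTL to 0 nM in the double knockdown. RNA was taken 48 h after transfection, and polyA RNA was sequenced as 100 bp pairs with a stranded kit on a HiSeq 2500. The labels number the 2 libraries of each group without saying whether they came from separate cultures or were handled in pairs, and they give no batch or date.

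According to the submitters' processing notes, reads were trimmed with cutadapt, aligned to hg19 with TopHat and analysed with DESeq, with no versions given. The read counter and the gene annotation are not stated. The authors' 3 deposited gene tables compare each knockdown with siCTL and give per gene a mean of normalized counts over the libraries, a log2 fold change with its standard error, a p-value and an adjusted p-value. The tables hold 0 columns of values per library. Each table has 19426 genes, of which 16457 symbols have a mean above 0. In all 16457 of these genes the authors' p-value equals, within 1%, the two-sided normal tail of the log2 fold change over its standard error. The adjusted p-value is absent below a mean that differs between tables, and the lowest mean with one is 10.7 for siDDX5/17, 79.0 for siREST and 3.65 for the double knockdown. For siDDX5/17 the median standard error is 0.13 at means below 10, under the 0.147 of all tested genes. Low counts give wider errors without shrinkage, so the fold changes appear shrunken toward 0 in weakly expressed genes. Notes in the sheets mention filters at a log2 fold change of 0.35 and a false discovery rate of 0.05.

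The authors' 6 deposited splicing tables compare pairs of groups, with 5 classes of event each. Per library they give the percent spliced in (PSI, the inclusion of an event) as a fraction, with a p-value from a generalized linear model and a corrected p-value, per the file headers. Parameter sheets state an unpaired test, a threshold of 0.05 on p and a minimum change of 10 points. The tables list the events that passed, and count sheets give the number tested. The program that called the events is not stated, and the number of reads behind each PSI value is not in the columns.

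Depth per library is unknown. The labels give an average over libraries of 60 × 1e+06 read pairs, and the mean normalized counts sum to 40226770 over all genes. The 10 most abundant genes take 6.16% of them. Without counts per library or reads per event, no interval for counting error was computed, and precision is given by the authors' standard errors or by both PSI values of a group.

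A gene was called when the authors' adjusted p-value was under 0.05, for each knockdown against siCTL. The comparisons of the double knockdown with each single knockdown, and of the double with the sum of both singles, had been intended as a description. After the tables had been seen, a test was added. Differences of the authors' log2 fold changes were divided by the root of the sum of the squared standard errors. This is an upper bound because the tables share the siCTL libraries. Two-sided normal tails were adjusted by the Benjamini-Hochberg method over the 13197 genes with an adjusted p-value in both tables that contain siDDX5/17. An alternative standard error assumed equal variance in all groups. Both were tested on simulated data with 200 changed genes among 13197. For the double knockdown against siDDX5/17 at 2-fold, the upper bound recovered 75.2% of changed genes with 0.1% false calls, and the alternative recovered 89.3% with 5.5%. For the departure from the sum, the upper bound recovered 61.0% at 2-fold with 0.3% false calls.

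The grouping, the thresholds, 28 gene lists, the tests on them, the rule for naming genes and most alternatives were fixed before the data were examined. Of 800 list entries, 776 were found in the tables, 23 of them under an older symbol. For each list and comparison, members called over all genes and members called with the p-values adjusted over the list alone were counted. The median log2 fold change was placed among those of 10000 random lists matched on mean expression in 20 bins. Fisher's exact test compared called members with the other tested genes. Both were adjusted by the Benjamini-Hochberg method over 134 tests of a list in a comparison, and lists with fewer than 3 tested members were left out of these tests. On simulated data, lists of 25 members with no shift passed the 97.5th percentile in 4 of 100 draws, and lists shifted by 0.1 on the log2 scale did so in 70 of 100.

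Genes were named by this rule: DDX5, DDX17 and REST everywhere; per comparison with siCTL, the 10 called genes with the largest rise and the 10 with the largest fall that have an ordinary gene symbol and a mean normalized count of at least 100 in the higher group, as estimated from the deposited mean and fold changes; per list, up to 4 members with the smallest adjusted p-value. For splicing, the rule took the 5 listed exon skipping events with the largest rise and the 5 with the largest fall per table, and events in REST or in genes of the list of splicing regulators. Exons were counted once per position, and events were matched between tables by exact coordinates. The overlap of spliced and changed genes was compared with random gene sets matched on expression.

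To look for matches of an siRNA seed, a 7-base word scan was run over the longest annotated 3′ UTR (GENCODE release 29) of genes with a mean of at least 100. Of 11362 such genes, 10939 (96.3%) had a 3′ UTR of at least 50 bases. The regression adjusted for UTR length, base composition and mean expression, and p-values of 16195 words were corrected by Bonferroni. Data were simulated with the spread of the siREST log2 fold changes and with commonly carried words. A word that lowered its genes by 0.05 on the log2 scale was found in 20 of 20 runs. With no effect, any word passed in 1 of 20. The spread of siDDX5/17 was not simulated, so this recovery does not apply to it. The strongest word had an SE of 0.0257 there (275 genes), against 0.0047 after siREST (1261 genes).

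Alternatives were an adjusted p-value under 0.01, minimum changes of 1.5-fold and 2-fold, minimum means of 10 and 100, the authors' filter at 0.35, the equal-variance standard error, a minimum of 20 PSI points, other ways to match events, another background, and leaving out each library in turn for PSI. No count model was fitted, because the tables hold statistics instead of counts. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.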

Results

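Gene expression and splicing were measured by RNA sequencing in SH-SY5Y, a human neuroblastoma cell line, after siRNA against the RNA helicases DDX5 and DDX17, against the transcriptional repressor REST, or against all 3 genes. The 8 libraries formed 4 groups of 2: siCTL, siDDX5/17, siREST and the double knockdown. All expression values below are the authors' deposited log2 fold changes with their standard errors (SE), or differences between these. Values per library were given for splicing only. Depth per library is unknown, and the median SE of tested genes was 0.147 for siDDX5/17, 0.139 for siREST and 0.152 for the double knockdown.

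The first question was whether each siRNA lowered its target. In the authors' deposited table, DDX5 fell by 2.10 ± 0.14 on the log2 scale after siDDX5/17 (adjusted p of 2.52e-46), to 23.4% of siCTL, and changed by -2.01 ± 0.14 in the double knockdown. DDX17 fell by 1.84 ± 0.12 after siDDX5/17 (adjusted p of 7e-46), to 27.9% of siCTL, and changed by -1.94 ± 0.12 in the double knockdown. After siREST alone DDX5 changed by -0.01 ± 0.14 and DDX17 by 0.03 ± 0.12. REST RNA fell by 0.68 ± 0.09 after siREST (adjusted p of 1.18e-09), to 62.5% of siCTL, and changed by -0.53 ± 0.09 in the double knockdown (adjusted p of 1.92e-07), to 69.3%. After siDDX5/17 alone REST rose by 0.24 ± 0.09, with an adjusted p of 0.0378 that passes 0.05 but not 0.01. Against siDDX5/17, REST in the double knockdown lay lower by a log2 difference of -0.77 (upper-bound SE 0.13). Against siREST it differed by 0.15 (SE 0.13), which did not pass the threshold.

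**Figure D1:**
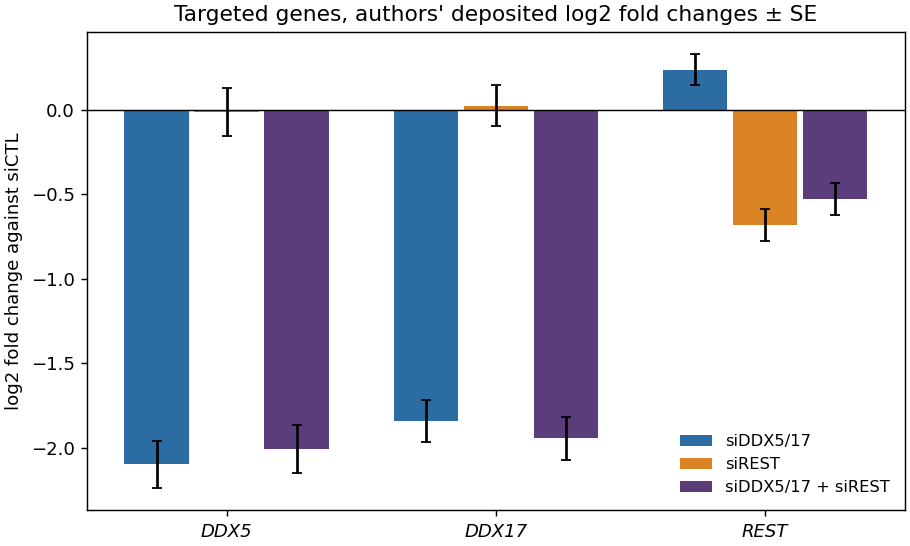
Log2 fold changes of DDX5, DDX17 and REST against siCTL in the 3 knockdowns, from the authors' deposited tables, with bars for values and whiskers for 1 SE. DDX5 and DDX17 lay near -2 wherever their siRNA was used, and REST reached -0.68 after siREST.

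The comparison of siDDX5/17 with siCTL asked which genes depend on the helicases. Of 13197 tested genes, 3757 (28.5%) were called, 1788 higher and 1969 lower. Their median absolute log2 fold change was 0.56, and 337 rose and 184 fell by at least 2-fold. The largest rises among named genes were those of NPC1L1 (3.78 ± 0.29), LEFTY1 (3.66 ± 0.27), SERPINF2 (3.23 ± 0.29) and ESPNL (3.22 ± 0.26). MYO1G, FCRL6, CACNG1, PDZD3, C7orf61 and FERMT3 followed with log2 fold changes from 3.20 down to 2.91. Mean normalized counts of these genes were low, from 66.0 for FCRL6 to 341 for NPC1L1. Apart from DDX5 and DDX17, the largest falls were those of HSPG2 (-1.88 ± 0.19), SLC37A4 (-1.83 ± 0.16), ENOSF1 (-1.81 ± 0.15), C11orf9 (-1.80 ± 0.23) and INPPL1 (-1.79 ± 0.12). SCARA3 and SCUBE1 lay at -1.71 and -1.63. Adjusted p of the named genes ran from 1.11e-47 for INPPL1 to 1.74e-10 for SCUBE1.

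The comparison of siREST with siCTL asked which genes depend on REST. Of 11567 tested genes, 134 (1.16%) were called, 70 higher and 64 lower, and at an adjusted p under 0.01 the split was 45 higher and 48 lower. Only 3 rose and 1 fell by at least 2-fold. VGF rose by 1.12 ± 0.17, CDKN1A by 1.12 ± 0.20 and SCG2 by 1.08 ± 0.12. PHLDA3, EDA2R, NELL2, TRIM67, DISP2, PTPRR and CKMT1B rose by 0.99 to 0.75, and NELL2 had the weakest evidence, with an adjusted p of 0.0117. Among genes that the naming rule covers, the largest falls were those of HTRA1 (-0.99 ± 0.23), SVEP1 (-0.89 ± 0.21), MFSD9 (-0.84 ± 0.13), FAM100B (-0.83 ± 0.16) and SLC7A1 (-0.80 ± 0.16). MTDH, BZW1, CREB3L2, PDZD11 and GALC lay between -0.77 and -0.72. Of these 10 lower genes, 7 carried the 7-base word CAGGCAA in an annotated 3′ UTR, all but SVEP1, PDZD11 and GALC.

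In the double knockdown, 6075 of 14011 tested genes (43.4%) were called, 2965 higher and 3110 lower, while of those changed by at least 2-fold 589 were higher and 485 lower. CDKN1A rose by 4.76 ± 0.20, with an adjusted p of 9.74e-119, the largest rise among the named genes. NPC1L1, LEFTY1, SLC24A2, GDF15, ARHGAP30, MYO1G, C7orf61, CACNG1 and MIOX followed with log2 fold changes from 3.59 down to 2.93. HSPG2 fell by 2.49 ± 0.19 and SCUBE1 changed by -2.42 ± 0.24. LINGO4, XKR5, GALC, C1orf173, ENOSF1, IGFBP5 and DUSP2 lay between -2.11 and -2.05. GALC, at -0.72 after siREST alone, reached -2.08 ± 0.13.

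Genes called in both single knockdowns were counted among the 11567 genes tested in both. Higher in both were 32, where independent lists would share 9.49, and lower in both were 17 against 10.5. Opposite changes were seen in 7 genes lower after siDDX5/17 and higher after siREST (11.5 for independent lists) and in 7 of the reverse kind (8.68). Both comparisons use the same siCTL libraries. In simulated unchanged groups compared with shared controls, 0 genes were called in both. Unchanged groups give few calls at all, so this cannot show how much of the observed sharing comes from the siCTL libraries. The covariance of the log2 fold changes across genes was 0.012 in the simulated groups. The observed covariance across genes was 0.011. The Pearson r was 0.172, against 0.50 in the simulated unchanged groups. These r values cannot be compared, because the siDDX5/17 effects widen the observed spread and the simulation holds none. The observed covariance did not exceed the simulated one, so it gives no evidence of agreement between the knockdowns. Genes are not independent replicates, so no p is given for correlations across genes.

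Each single knockdown was then compared with its effect in libraries that it does not share. The double knockdown minus siDDX5/17 holds the siREST effect without siCTL. All 70 genes called higher after siREST were also higher there, with medians of 0.55 and 0.71, and all 64 called lower were lower, with medians of -0.58 and -0.70. Across 11567 genes, r was 0.659. Control siRNA fell from 20 nM to 0 nM in this difference and from 40 nM to 20 nM in siREST against siCTL. Agreement between them alone therefore cannot separate siREST from the loss of control siRNA. In siDDX5/17 against siCTL, control siRNA also fell from 40 nM to 20 nM. The list of classic REST targets had a median of 0.04 in that comparison, inside its random range (-0.081 to 0.092), against 0.30 after siREST. For that list, these values argue against loss of control siRNA as the cause, unless loss of the helicases offset it. The double knockdown minus siREST holds the siDDX5/17 effect, with the same limit from control siRNA. There, 1765 of 1788 genes called higher and 1953 of 1969 called lower kept their sign, and r was 0.901.

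By the test added after the tables were seen, 473 of 13197 genes differed between the double knockdown and siDDX5/17, 264 higher and 209 lower. VGF lay higher by 1.67 (SE 0.24), SCG2 by 1.51 (SE 0.18) and CDKN1A by 2.02 (SE 0.29). Between the double knockdown and siREST, 2883 genes differed, 1291 higher in the double and 1592 lower, and at 2-fold or more 438 were higher and 361 lower. CDKN1A lay higher by 3.64 (SE 0.29). Of the 3242 genes called both after siDDX5/17 and in the double knockdown, 2367 (73.0%) lay farther from 0 in the double, where the median absolute log2 fold change was 0.74 against 0.58. A departure from the sum of both single effects passed the threshold for 25 genes, 14 above the sum and 11 below it. At an unadjusted p under 0.05 it passed for 378, fewer than the share of 0.05 that chance would give among 13197 genes. That count adds no evidence of further departures. At an adjusted p under 0.01 the departure passed for 1 gene above and 4 below. The median SE of this quantity was 0.255, and on simulated data 13.1% of departures of 1.5-fold were recovered.

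**Figure D2:**
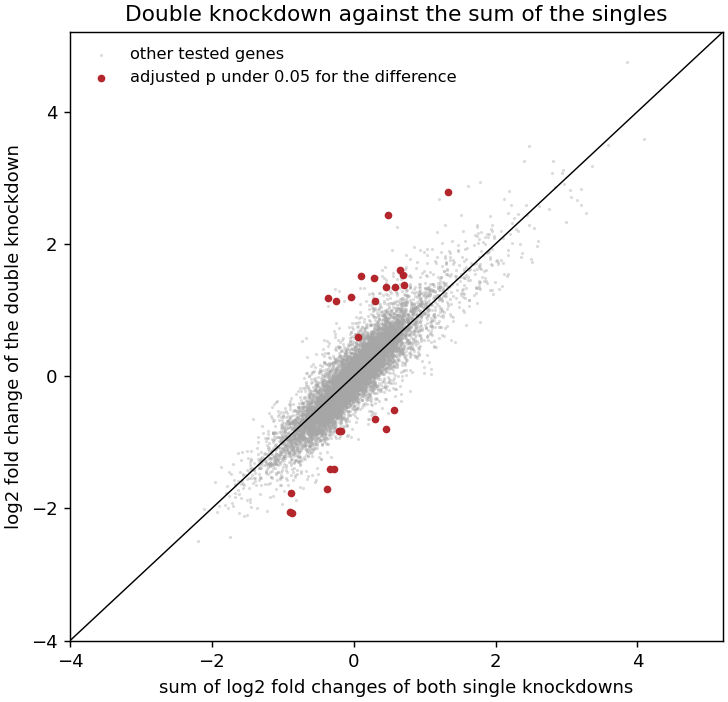
Log2 fold change of each gene in the double knockdown against the sum of its log2 fold changes in the single knockdowns. The line marks equality, and the 25 red points are the genes whose departure passed an adjusted p of 0.05, 14 above the line and 11 below it.

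Lists of genes addressed known programs of these proteins and of the cell. Of the list of classic REST targets, 20 of 75 tested members were higher and 0 lower after siREST, 36 and 0 when adjusted over the list alone. The list median was 0.30, above the range of matched random lists (-0.03 to 0.03). SCG2, SCG3 (0.65), VGF and STMN3 (0.58) had the smallest adjusted p. After siDDX5/17 the list went both ways, with 11 of 84 higher and 6 lower and a median of 0.04 inside the random range. VGF rose, whereas RPH3A (-0.68), KIF1A (-0.70) and MMP24 (-0.60) fell. In the double knockdown 52 of 87 members were higher and 2 lower, with a median of 0.53. VGF reached 2.67, SCG2 1.90, CHGB 1.62 and RAB3C 1.33. Against siDDX5/17, the double knockdown had 29 of 84 members higher and 0 lower.

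The median of the p53 target list lay above its random range in all 3 knockdowns. After siDDX5/17, 19 of 26 tested members were higher and 1 lower, with a median of 0.62 (random range -0.15 to 0.13). After siREST, 5 were higher and 0 lower, 11 and 1 when adjusted over the list alone, with a median of 0.34. In the double knockdown 23 of 27 were higher and 1 lower, with a median of 1.16. CDKN1A (2.73, 1.12 and 4.76 in siDDX5/17, siREST and the double), PHLDA3 (1.85, 0.99 and 2.86) and TP53INP1 (1.52, 0.43 and 2.20) were among the members with the smallest adjusted p in each. The medians of the differences from siDDX5/17 (0.58) and from siREST (0.91) also lay above their random ranges. Cell cycle genes fell. After siDDX5/17, 1 of 49 was higher and 21 lower with a median of -0.40, and in the double knockdown 0 were higher and 40 lower with a median of -0.77. After siREST 0 were called in either direction, and the median was -0.01. MCM3, MCM5 and E2F1 were at -1.15, -1.44 and -1.12 in the double knockdown.

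Immediate early genes were higher in 12 of 16 tested after siDDX5/17 (median 0.58), in 0 of 14 after siREST (median -0.02) and in 14 of 17 in the double knockdown (median 1.20), with 0 lower in each. KLF6 rose by 1.18 after siDDX5/17 and DUSP6 by 1.47 in the double. Of 24 tested genes of the unfolded protein response, 4 were higher and 1 lower after siDDX5/17 (median 0.09), 0 were called after siREST, and 16 were higher and 1 lower in the double knockdown (median 0.55). DDIT3 rose by 0.64 after siDDX5/17 and by 1.56 in the double. Cholesterol synthesis genes had a median of -0.29 after siDDX5/17, with 0 of 22 higher and 7 lower. Their median was 0.03 after siREST with 0 called, and in the double knockdown it was -0.19, with 1 higher and 6 lower, inside the random range. Proneural factors were higher in 6 of 14 and lower in 0 after siDDX5/17, were called in 0 of 11 after siREST, where the median of 0.12 lay above its random range (-0.08 to 0.09), and were higher in 9 and lower in 2 of 14 in the double. Their median of 0.71 in the double lay above the random range, and SOX4 rose by 0.64 and 0.74.

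The adrenergic state list had 7 higher and 3 lower of 22 after siDDX5/17 (median 0.19), 1 higher and 0 lower of 21 after siREST (median 0.02) and 12 higher and 3 lower in the double (median 0.39). TFAP2B rose by 0.67 and 0.83, while DDC fell by 0.86 after siDDX5/17. Its counterpart, the mesenchymal state list, had 5 higher and 3 lower of 18 after siDDX5/17, 0 called of 14 after siREST, and 7 higher and 5 lower in the double, with medians inside the random ranges. Interferon response genes had 3 higher and 4 lower in both siDDX5/17 (of 22) and the double (of 27), with medians of 0.02 and -0.04, and 0 of 15 were called after siREST. ISG20 (1.89 and 2.28) and DDX58 (1.20 and 1.39) rose, whereas RSAD2 was at -1.73 in the double.

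**Figure D3:**
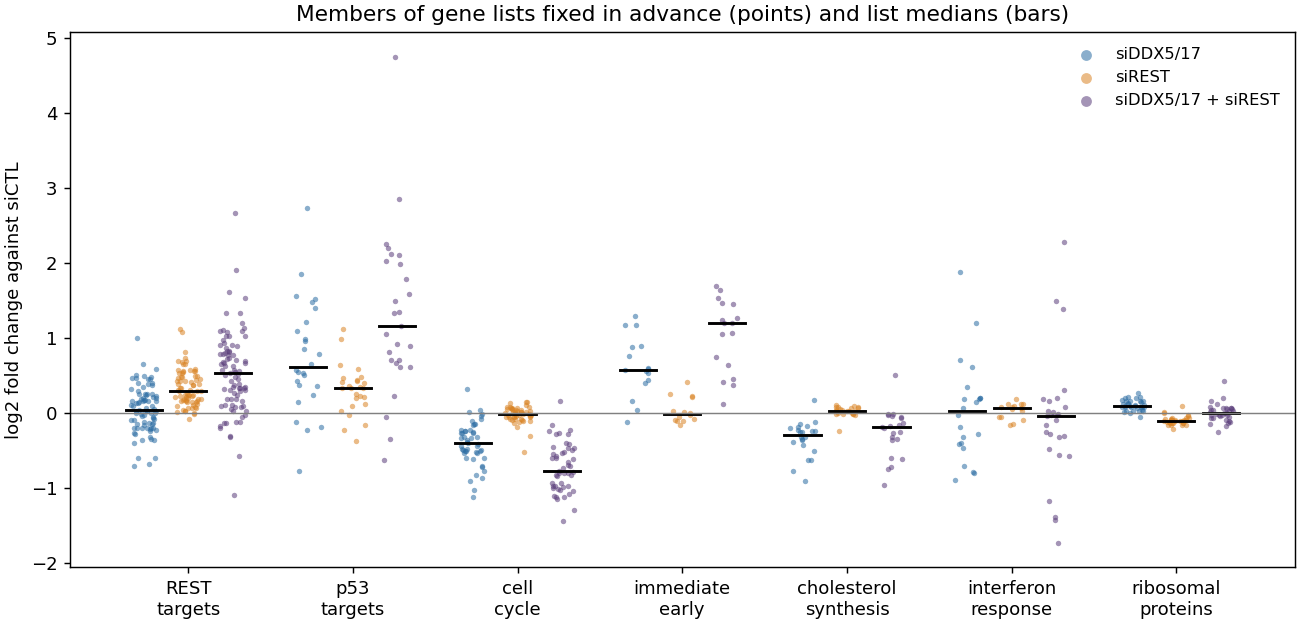
Log2 fold changes against siCTL of the members of 7 gene lists in the 3 knockdowns, one point per gene and a bar at each list's median. REST targets and p53 targets had their highest medians in the double knockdown (0.53 and 1.16), cell cycle genes their lowest (-0.77).

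The other lists are summarised as members higher and lower after siDDX5/17, siREST and the double knockdown in turn. Of all tested genes, 28.5% were called after siDDX5/17 and 43.4% in the double, so such counts alone do not mark a response. SRF and YAP targets with the actin cytoskeleton had 6 and 2, 2 and 0, and 8 and 1, with a median of 0.31 in the double. Axon guidance and adhesion genes had 6 and 7, 0 and 1, and 14 and 14. In the double knockdown 71.8% of them were called, against 43.3% of other genes (Fisher's exact test, adjusted p of 0.00353). Extracellular matrix genes had 6 and 9, 0 and 1, and 8 and 11, and their median after siREST, -0.09, lay below its random range (-0.05 to 0.05). The Notch pathway had 5 and 4, 0 and 0, and 6 and 5. Wnt targets had 3 and 2, 0 and 0, and 3 and 6. Splicing regulators had 10 and 7, 1 and 0, and 18 and 7, and CELF3 rose in each (0.67, 0.54 and 1.37). Their called share was 24.6% after siDDX5/17 and 35.2% in the double, not above the 28.5% and 43.4% of other genes. DEAD-box helicases had 4 and 9, 0 and 0, and 7 and 10. REST corepressors had 3 and 2, 0 and 0, and 3 and 4. Factors of microRNA processing had 2 and 2, 0 and 0, and 2 and 4. Hosts of neural microRNAs had 1 and 1, 0 and 0, and 0 and 1. Hypoxia and glycolysis genes had 1 and 2, 0 and 0, and 5 and 4, with a median after siREST of -0.08 below its random range (-0.04 to 0.05), and replication histones 3 and 0, 0 and 0, and 1 and 1. Mitochondrially encoded genes had 0 and 0, 0 and 0, and 1 and 0.

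Ribosomal protein genes had 0 of 34 called in all 3 comparisons, with medians of 0.09, -0.10 and 0.00 in siDDX5/17, siREST and the double. The siREST median lay below its random range (-0.03 to 0.04). Genes that mark other cell types were read for foreign cells. Fibroblast markers had 3 higher and 2 lower, 0 called, and 2 higher and 2 lower in the same order. Epithelial markers had 2 and 0, 0 and 0, and 2 and 1. Of 10 blood markers, only LYZ was tested, in the double knockdown alone, and it was not called. The list of the targeted genes themselves had 1 higher and 2 lower after siDDX5/17, 0 and 1 after siREST, and 0 and 3 in the double. Across all lists, the counts of 0 above come from the authors' adjusted p, at which siREST had 134 called genes in total. At an unadjusted p under 0.05 it had 708. Chance alone gives many at that threshold, so the 708 are no evidence of further change.

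Splicing tables asked which exons depend on the helicases and on REST. PSI is the percent of transcripts that include an event, and n = 2 libraries per group throughout. Of 36235 exon skipping events tested for siDDX5/17 against siCTL, the authors listed 3041, at 2972 distinct exons of 2339 genes. Inclusion fell at 2651 of these (89.2%) and rose at 321, and the median absolute change was 0.180 as a fraction. For siREST against siCTL, 3 of 29604 were listed, 1 more included and 2 less. The double knockdown had 3173 distinct exons against siCTL (2812 less included, 361 more), 3071 against siREST (2712 less, 359 more) and 41 against siDDX5/17 (21 less, 20 more). In siREST against siDDX5/17, 2530 of 2849 exons were more included. The tables hold events that the authors selected, so no further test was made on single events.

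**Figure D4:**
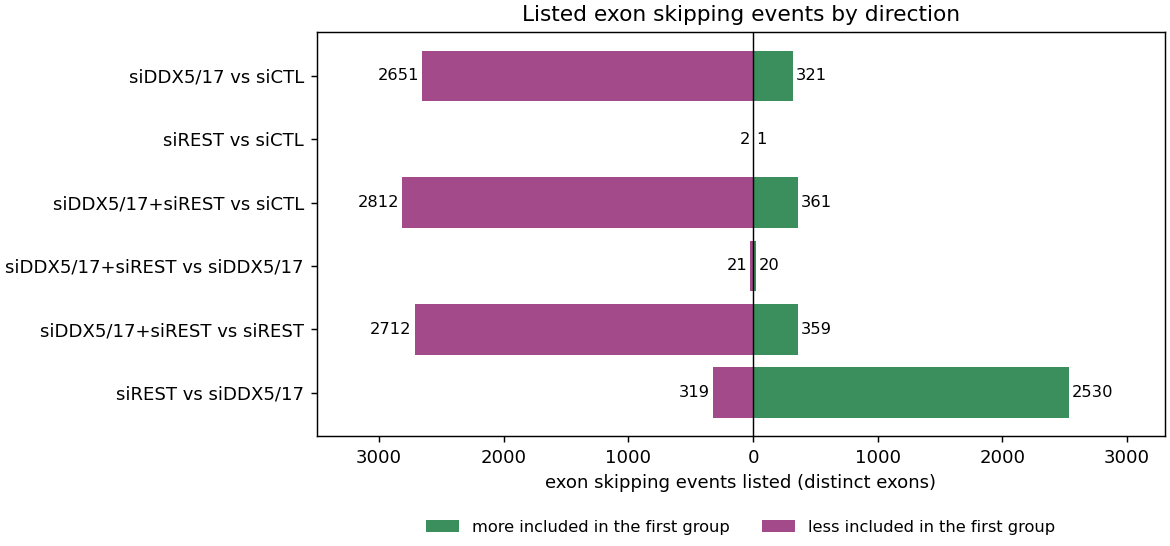
Number of distinct exons listed by the authors as skipping events in each of the 6 comparisons, those less included in the first group to the left of 0 and those more included to the right. The 4 comparisons that contrast siDDX5/17 or the double knockdown with a group lacking that siRNA had 2849 to 3173 exons, the other comparisons 3 and 41.

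The other event classes were likewise few after siREST. For siDDX5/17, siREST and the double knockdown against siCTL, alternative acceptors were listed at 258, 3 and 294 positions, alternative donors at 381, 4 and 426, and mutually exclusive exons at 31, 1 and 29. Skipping of several exons at once was listed at 1471, 1 and 1630 positions, and after siDDX5/17 inclusion fell at 1370 of them (93.1%).

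The largest falls in inclusion after siDDX5/17 included exon 6 of TBX2 (hg19, chromosome 17, 59482563 to 59483197), at 14.7% and 20.7% against 100.0% in both siCTL libraries. Exon 10 of ABCB6, which the table also assigns to ATG9A, changed by -74.2 points, exon 7 of CPT1C by -73.0, exon 24 of SEC31B by -72.5 and exon 14 of MKNK1 by -70.1. Exon 5 of C16orf55 (chromosome 16, 89726948 to 89727891) rose most, to 89.1% and 87.5% from 23.1% and 35.3%. Exon 8 of TERF1 rose by 41.0 points, exon 2 of CHCHD4 by 39.0, exon 25 of EIF4G3 by 38.7 and exon 3 of SULT1C4 by 36.5. Among splicing regulators, exon 10 of SRRM3 changed by -32.8 points, exon 2 of SRRM2 by -31.1 and exon 12 of PTBP2 by -26.7, while exon 3 of RBM39 rose by 25.2. The 3 exons listed after siREST were exon 9 of TCTN1 (15.6 points), exon 7 of YIF1A (-11.8) and exon 11 of STK38 (-10.2).

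Of the 2972 exons listed for siDDX5/17 against siCTL, 2057 (69.2%) were also listed for the double knockdown against siREST, which shares no library with it. All 2057 changed in the same direction, with an r of 0.932 across exons. The 3 exons listed after siREST included 0 of the 41 listed for the double knockdown against siDDX5/17. Genes with a listed event of exon skipping were compared with genes whose RNA level changed. After siDDX5/17, 865 of 2259 such genes (38.3%) were called in expression, against 678 on average in random sets matched on expression (central range 640 to 715). Of the 865, 638 were lower, against 382 in random sets. In the double knockdown 1281 of 2397 (53.4%) were called, against 1171 in random sets, with 840 lower against 641. Each permutation p was 0.0002, the smallest these draws can give.

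Exon 5 of REST itself (hg19, chromosome 4, 57793781 to 57793830, 50 bases) had the largest rise among exons listed for the double knockdown against siDDX5/17. Its PSI was 34.4% and 32.0% in siCTL, 30.1% and 28.1% in siDDX5/17, 38.7% and 37.0% in siREST, and 90.9% and 70.7% in the double knockdown. The mean rise over siDDX5/17 was 51.7 points. Both double knockdown libraries lay above the other 6, although they differed from each other more than the libraries of any other group. SFT2D1 exon 2 rose by 41.5 points in the same comparison, NECAB3 exon 3 by 36.3, ASPH exon 4 by 34.3 and CPEB2 exon 6 by 31.2. Inclusion fell most in HSPA14 exon 9 (-23.5 points) and DMXL2 exon 34 (-20.5).

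**Figure D5:**
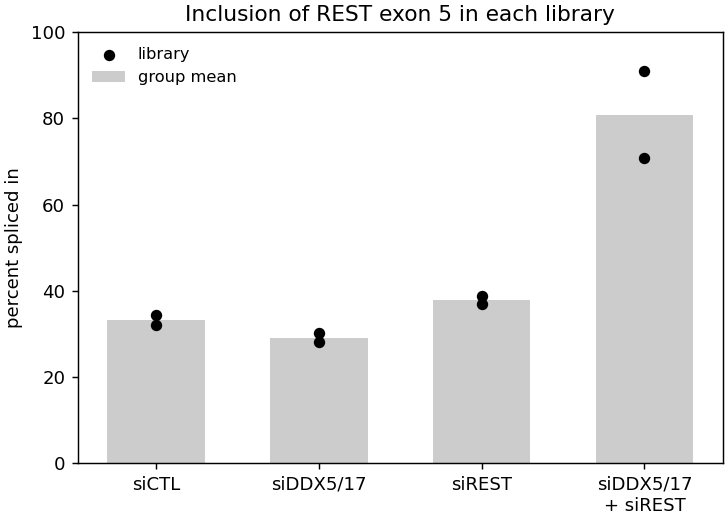
Percent spliced in of REST exon 5 in each of the 8 libraries (points) with the mean of each group (bars). Both double knockdown libraries (90.9% and 70.7%) lay above all others, which ran from 28.1% to 38.7%.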

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

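The test of departure from the sum of both single knockdowns, the tests on the siCTL libraries, on interferon genes and on MDM2, and the counts for words other than the strongest of each siRNA, were chosen after the results were seen, and the search for siRNA seed words was set before its result.

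The effect of the double knockdown differed from the sum of both single effects, by a test of the difference itself, in 25 of 13197 genes. The value lay above the sum in 14 genes and below it in 11. The upper-bound SE makes this test conservative, and the tables give no values per library to check it. Among genes that the naming rule covers, C1orf173 lay below the sum by a log2 difference of -1.19, IGFBP5 by -1.15, EGLN3 by -0.89 and PLXNA1 by -0.62. ACTG1 lay above the sum by 0.95, NEUROG2 by 1.20 and SLC18A2 by 1.95. Of these 7, only ACTG1 (adjusted p of 0.00105) passed 0.01, and the others had adjusted p from 0.0118 to 0.0467. The other genes past 0.01 were C18orf1 (-1.33), SMAD6 (-1.26), UQCRB (-1.12) and AIF1L (-1.08), chosen after their values were seen. ACTG1 rose by 0.23 after siDDX5/17 and by 0.42 after siREST. SLC18A2, with 0.46 after siDDX5/17, 0.03 after siREST and 2.44 in the double knockdown, had a mean normalized count of 66.3. Departures on the log2 scale are departures from multiplied effects. Control siRNA was at 40 nM in siCTL, 20 nM in each single knockdown and 0 nM in the double knockdown. An effect proportional to this dose on the log2 scale cancels in the departure. An effect of control siRNA that is not proportional to dose cannot be separated from the departures.

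The first pattern weighed was the set of 64 genes lower after siREST. REST is a repressor, so its loss would raise its direct targets. Chance values in the siCTL libraries are argued against by a comparison that uses neither siCTL nor siREST alone: the median of the 64 genes in the double knockdown minus siDDX5/17 was -0.704, where matched random lists ran from -0.072 to 0.051. Seed matches of the siRNA remain open and had the values they need. The 7-base word most strongly tied to lower values after siREST was CAGGCAA, carried in the 3′ UTR by 1261 of 10939 genes, whose log2 fold change was lower by a difference of -0.067 (Bonferroni-adjusted value 4.7e-41 over 16195 words). In the double knockdown minus siDDX5/17 the same word ranked 1st, with a difference of -0.098. Of the 61 lower genes with an annotated UTR, 34 (55.7%) carried it, against 14.3% in draws matched on UTR length and mean expression, with a permutation p of 0.0001, the smallest these draws can give. The word was chosen on the same siREST values that call these genes, so the recurrence in the libraries without siCTL is the independent part of the evidence. The word occurs in REST mRNA, as do 30.3% of all 7-base words. A candidate explanation for part of the lower genes is therefore direct silencing by a strand of the siREST duplex. A further pair of overlapping words, TCTAACT and CTAACTA, also passed after siREST (Bonferroni-adjusted values 2.59e-12 and 2.91e-12) and in the double knockdown minus siDDX5/17 (4.68e-06 and 0.000102), and both occur in REST mRNA. Of the 27 lower genes without CAGGCAA, 9 carried at least 1 of the pair, against 14.6% expected in matched draws (permutation p of 0.0072), so a seed effect is open for some of these as well. Together, 43 of the 61 genes (70.5%) carried CAGGCAA or 1 of the pair, against 28.7% expected. AGGCAAA and AAGGCAA, which share the bases AGGCAA with CAGGCAA, ranked 2nd and 3rd after siREST (Bonferroni-adjusted values 4.52e-36 and 4.46e-13). They held these ranks in the double knockdown minus siDDX5/17 (4.27e-20 and 1.96e-10), and both occur in REST mRNA. At least 1 of CAGGCAA, AGGCAAA and AAGGCAA was carried by 49 of the 61 genes (80.3%), against 35.2% expected. Loss of REST stays open as a cause, with or without these words, as does the lower dose of control siRNA. Neither was tested. The siDDX5/17 group had the same lower dose of control siRNA. Of the 64 genes, 17 were called lower there (10.5 for independent lists) and 7 higher. CAGGCAA was not among the 6 words most strongly tied to lower values after siDDX5/17. Loss of the helicases also acts on those values, so they do not decide for the 64 genes. Words tied to higher values passed in the double knockdown minus siDDX5/17, where GCGTACA ranked 1st (Bonferroni-adjusted value 0.000384). The 6 strongest words there all passed, the last at 0.00993. GCGTACA, TGCGTAC, GCGTACT and AGCGTAC share the bases GCGTAC, and TACTTCG and ATACTTC share TACTTC. None passed after siREST, where CGCGGAG ranked 1st (0.147). The same held after siDDX5/17 (GGGCGCC, 0.31) and in the double knockdown minus siREST (TTGGGGG, 0.102). Headers of the PSI values name the control siRNA as siGL2, without its sequence. Whether less control siRNA raised genes with such words was not tested, so this stays open. The sequences of the siRNAs are not given in the labels, so CAGGCAA and the other words could not be compared with them.

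The second pattern weighed was the set of genes lower after siDDX5/17, where the strongest word was CGGCACA, carried by 275 genes, with a difference of -0.122 (Bonferroni-adjusted value 0.0311). In the double knockdown minus siREST it ranked 6th and did not pass over all words (difference of -0.136, Bonferroni-adjusted value 0.164), while its one-sided p as a single word was 5.06e-06. Of 1830 lower genes with a UTR, 70 (3.83%) carried it, against 2.11% in matched draws. The overlapping words CTGCAGG and GCTGCAG also passed (0.0361 and 0.0374), in 2228 and 2421 genes with smaller differences of -0.051 and -0.050, and passed again in the double knockdown minus siREST (0.0192 and 0.00639). At least 1 of the 3 words was carried by 717 of the 1830 lower genes (39.2%), against 29.7% expected in matched draws, which did not account for base composition. The 3 words were the strongest on the same values that call these genes, so their excess there is no independent evidence. The values of CGGCACA met the conditions set for a seed effect, which asked for the single-word p and not for a Bonferroni pass in the libraries without siCTL. Such an effect could account for part of the lower genes, of unknown size. The full sequences of these 3 words are absent from DDX5 and DDX17 mRNA, which the guide strand of an siRNA against them would match. Shorter parts of the words were not looked for there, so this absence does not exclude a seed of the guide strand. CTGGCCA, looked at after the results had been seen, occurs in DDX17 mRNA but not in DDX5 mRNA. It did not pass after siDDX5/17 (0.0651) but passed in the double knockdown minus siREST (0.00161). Of the 1830 lower genes, 513 carried it, against 401 expected (permutation p of 0.0001, the smallest these draws can give). CTGGCCA ranked 4th on the same values that call these genes, so this excess is no independent evidence. GAAGATG, also looked at after the results, occurs in both DDX5 and DDX17 mRNA. It passed in the double knockdown minus siREST (4.14e-05) but not after siDDX5/17 (0.224). A seed of the guide strand therefore stays open, as does one of the other strand. Other roles of the words in the 3′ UTR were not tested.

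The third pattern weighed was the rise of p53 target genes, read as a rise of the list median. Low chance values in the siCTL libraries are argued against by the list medians in comparisons without siCTL, of which the smaller was 0.579, for the double knockdown minus siDDX5/17, above its random range. An interferon response to transfected RNA remains open: the interferon list had a median of -0.038 in the double knockdown, but its members went both ways, with ISG20 at 2.28, DDX58 at 1.39 and RSAD2 at -1.73, which decides nothing. A seed match in MDM2, which encodes the main inhibitor of p53, is likewise open for the rise after siREST. Its longest 3′ UTR (10837 bases) carries 2 sites of CAGGCAA and 4 of AGGCAAA. MDM2 changed by -0.368 after siREST, with an adjusted p of 0.17 that did not pass the threshold. MDM2 rose by 0.43 after siDDX5/17, so a loss of its RNA was not seen there. MDM2 is itself on the p53 target list and its protein was not measured, so this rise decides nothing further. A response of p53 to loss of the helicases or of REST is the biological alternative, and it was not tested beyond the list itself. Each knockdown also received less control siRNA than siCTL, and an effect of that was not tested.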

How the results depend on the processing

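The equal-variance standard error and the authors' filter at a log2 fold change of 0.35 were chosen after seeing the data, and the other alternatives before.

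No paired analysis was possible because the gene tables hold no values per library and the labels do not say whether libraries of the same number belong together. For the same reason the alternatives of another tool, another normalization, a filter on low counts, a fit on the compared groups alone, another pseudocount, folds from values per library and, for expression, leaving out a library were not run, and a minimum of junction reads was not run because read numbers are not in the splicing columns. For splicing, PSI is given per library, but nothing states which values of different groups belong together. In TERF1 exon 8 and RBM39 exon 3 the first value was the higher in all 4 groups. In TBX2 exon 6 it was higher in the double knockdown and lower in siDDX5/17. Whether the order of values marks paired libraries was not tested. The fold changes of single genes are the authors' in every alternative, so their direction could not change, but the balance of higher and lower genes did.

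With a minimum of 1.5-fold, called genes were 1769 after siDDX5/17, 59 after siREST and 3261 in the double knockdown. Genes higher and lower in both singles were 8 and 4, and called list members were 107 after siDDX5/17 and 16 after siREST. With a minimum of 2-fold, called genes were 521, 4 and 1074 in the same order, 104 for the double against siDDX5/17, 799 for the double against siREST and 14 for the departure from the sum. Genes higher and lower in both singles were then 2 and 0, and list members 32, 3, 108, 22 and 73 over the 5 comparisons. These falls in number follow from the minimum itself. The majority turned at 2-fold in 3 comparisons: 64.7% of called genes were higher after siDDX5/17 against 47.6% with no minimum, 54.8% against 48.8% in the double knockdown, and 54.8% against 44.8% for the double against siREST. After siREST the share higher was 52.2%, but 47.5% at 1.5-fold and 48.4% at an adjusted p under 0.01. For the departure from the sum it was 56.0%, with 7 higher and 7 lower at 2-fold, and 20.0% at an adjusted p under 0.01. The cause was not tested.

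At an adjusted p under 0.01, 269 genes were called for the double against siDDX5/17, 1868 for the double against siREST and 5 for the departure from the sum. Shared genes were 16 higher and 11 lower, and list members for the double against siDDX5/17 were 49. With the equal-variance standard error, these comparisons had 1553, 5375 and 76 genes, which included all 473, 2883 and 25, and list members were 153 and 304. The smaller standard error is the cause, and simulated false calls rose to 5.5% for the first and second of these and 5.0% for the departure. Minimum means of 10 and 100 left each count of called genes within 1.5 times its value, as did the filter at 0.35 for the comparisons with siCTL.

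REST, at 0.24 after siDDX5/17, was not past the threshold at an adjusted p under 0.01, with either fold minimum or with the filter at 0.35. Its values of -0.68 after siREST and -0.53 in the double knockdown did not reach 2-fold, and -0.53 did not reach 1.5-fold. DDX5 and DDX17 stayed past every threshold tried where their siRNA was used. Of 57 named genes by comparison, 56 kept their call at an adjusted p under 0.01, all but NELL2, and 40 at 2-fold. With a minimum mean of 100, FCRL6, PDZD3 and MIOX dropped out because their means are lower.

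For exon skipping, an adjusted p under 0.01 left 0 exons after siREST and 22 for the double against siDDX5/17. A minimum of 20 points left 1258 exons after siDDX5/17, 0 after siREST, 1374 in the double, 10 and 1329 for the double against siDDX5/17 and siREST, and 1220 for siREST against siDDX5/17. Exons shared with the siDDX5/17 table at 20 points were 870 for the double against siREST, 941 for the double against siCTL and 1048 for siREST against siDDX5/17. No overlap could be given at 20 points for siREST, whose table had 0 such exons. Leaving out each library in turn and keeping changes of at least 10 points left 2556 to 2847 exons after siDDX5/17, 2 to 3 after siREST, 2767 to 3066 in the double, 31 to 41 for the double against siDDX5/17, 2665 to 2965 for the double against siREST and 2465 to 2731 for siREST against siDDX5/17. With genes above the lower quartile of expression as background, the share of spliced genes called in expression was 38.6% after siDDX5/17 and 55.5% in the double knockdown.

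Depth per library is unknown, so no limit from depth was set beyond the standard errors: departures from the sum of 1.5-fold were recovered in 13.1% of simulated genes and those of 3-fold in 87.4%.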

Other observations

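The tests on REST exon 5 and the look at the word GAAGATG were chosen after the results had been seen, and the genes SRRM3 and SRRM4 were chosen as known factors for very short exons.

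REST exon 5 was included at 80.8% on average in the double knockdown, 47.6 points above siCTL. One explanation would be that siREST removes transcripts without the exon and leaves those with it. Inclusion rose by only 4.64 points after siREST alone and changed by -4.08 points after siDDX5/17 alone, while REST RNA fell by 0.68 after siREST and by 0.53 in the double knockdown. Removal by siREST alone would have raised inclusion in both groups, which argues against it as the whole cause. The reads behind the values are unknown, and the double knockdown libraries stood at 90.9% and 70.7%.

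A hypothesis is that more of the microexon factors SRRM3 and SRRM4 may raise inclusion. SRRM3 was called in the double knockdown (1.11) but not after siDDX5/17 (0.30, adjusted p of 0.189) or siREST (0.43, adjusted p of 0.397). The rise of SRRM3 over siDDX5/17 was 0.81, with an adjusted p of 0.0267 by the added test. SRRM4 was also called higher in the double knockdown against siCTL. Among exons listed for the double knockdown against siDDX5/17, 8 exons of up to 30 bases were more included and 2 less, against 12 more and 19 less among longer ones (one-sided Fisher's exact test, p = 0.0269). The difference has the direction that the hypothesis needs. Limits remain. Exon 5, with 50 bases, is outside the class of up to 30 bases, so this comparison does not cover it. SRRM4 already rose by 0.46 after siDDX5/17 without a rise in exon 5. Short exons were also more often more included in siDDX5/17 against siCTL (26.8% of those of up to 30 bases against 10.6% of longer ones).

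The word GAAGATG ranked 1st for the double knockdown minus siREST, with a Bonferroni-adjusted value of 4.14e-05, and passed in the double knockdown against siCTL (0.00182). It ranked 6th after siDDX5/17, where it did not pass (0.224). Of 1830 genes lower after siDDX5/17, 311 carried it, against 282 expected in matched draws (permutation p of 0.0168). It occurs in both DDX5 and DDX17 mRNA, as do 4.83% of all 7-base words. GAAGATG is therefore among the words that leave a seed of the guide strand open.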
